A study of Pimephales promelas with 38 samples.

How the data were processed

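RNA from the liver of male fathead minnows was measured on 38 Agilent arrays with 1 colour (Cy3), 1 array per sample. The RNA was extracted with RNA STAT-60 and treated with DNase, and its quality was checked on a BioAnalyzer, per the labels' protocols. The deposited scanner files hold spot intensity per the file headers and columns, made with Agilent Feature Extraction 10.1.1.1 according to those headers, whereas the submitters' processing notes name version 9.5. The processed signal in these files was already background-subtracted and detrended within the array by that software, per the file headers, with a surrogate value where a spot fell to background, and was not normalized between arrays. The deposited value table of the series holds log2 values. They equalled log2 of the processed signal minus the array's median to within 0.011, and every column had a median of 0, which settles its scale, centring and direction. Its 196 missing values were all spots that the software had marked as non-uniform. Other filters that the authors applied are not given in the sources used here.

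The labels gave the group and replicate number of every sample. Per the labels' protocols, 18 fish were exposed per treatment, and 3 males and 3 females shared an aquarium, which makes 3 aquaria and 9 males per treatment. That is fewer than the 10 arrays of 5% primary effluent, and the aquarium of each fish is not given in the sources used here. Fish of 1 aquarium may not be independent. The sample titles hold, besides the replicate number, a number that differs between all arrays of an experiment. It may mark separate fish, but its meaning is not given in the sources used here, so p-values measure the spread between these arrays. The pair of arrays most alike was 5% secondary arrays 5 and 6 (r = 0.986 over the probes tested). Of 9590 probes above background on both, 16 were at least 4-fold apart. Whether they hold the same RNA is not given in the sources used here, and repeat arrays of 1 RNA would differ too. Each was kept as a sample, and their average was tried as an alternative. If they are repeats, the p-values of this group are too small.

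Control spots were left out, and spots marked as outliers (0 to 24 per array) were treated as missing. The main values were log2 of the processed signal minus the 75th percentile of the array. That percentile ran from 235.1 to 957.3 intensity units, and between 9837 and 12739 of 15208 probes per array were well above background. Probes well above background on at least 3 arrays were tested, 13185 in all. A probe that was not well above background on any array of a group has only a bound there. Group means were fitted over all 38 arrays in limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the packages statmod (version 1.5.0), jsonlite (version 2.0.0) and data.table (version 1.17.8). There were 9 contrasts: E2 against control in each experiment, each effluent group against its control, 5% against 0.5% primary effluent, the differences of the E2 and of the 5% effluent effects between the experiments, and control against control. Tests were two-sided with a threshold of adjusted p = 0.05 after Benjamini-Hochberg adjustment over probes. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

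The median log2 change of all tested probes was -0.14 for E2 in experiment a and within 0.1 of 0 in the other contrasts. With normexp background correction it was -0.22 and 0.18 for E2 in experiments a and b, -0.37 for the difference of the E2 effects, -0.14 for control b against control a and 0.14 for the difference of the 5% effects. With each array's median it was -0.17 for E2 in experiment a.

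Gene lists, cell type markers and a rule for named genes were fixed before the data were examined. The files describe all 15208 probes as unknown and name them by 14499 sequence names, called contigs here. None of these names was among the 64593 genes of the reference table of assembly fPimPro1.hap1.1 (0 matched), so 0 members of the lists and markers were measured, and no sequence could be placed on a chromosome. The rule was therefore replaced, before any group was compared, by the 2 probes with the largest rise and the 2 with the largest fall among called probes above background on every array of the higher group. For the differences of effects and the comparison of controls, every array of at least 1 group was required. Families of contigs with at least 5 tested probes (20 families) were tested as sets in place of the lists, with camera at a preset correlation of 0.01, with an estimated correlation, and with fry.

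Slide and scan day were the same division of the arrays, with 5 of each. The slide was added to the fit as a block, and comparisons were repeated within each slide that held both groups, with the spread pooled over all sets of arrays of 1 group on 1 slide. Correlations of fold changes across probes were set against 100 simulations of unchanged groups, and overlaps and correlations of pairs with the same controls were repeated with the controls split. The alternatives were quantile normalization, the array median, normexp (offset 50) on the mean and background signals, the deposited log2 values, no filter, a stricter filter, a minimum of 2-fold, a trended and robust variance, array weights, slide and replicate number as blocks, only the groups compared, and each replicate left out in turn.

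The fit was tested on simulated data, in which 100 of 13185 probes were changed by each of 2 log2 sizes and the noise was independent between probes and arrays. For a log2 change of 2 it recovered 66% for E2 in each experiment, 80% for 5% primary effluent, 60% for 0.5% primary effluent, 80% for 5% secondary effluent, 69% for 5% against 0.5%, 49% for the difference of the 5% effects, 56% for that of the E2 effects and 76% for the controls. For a log2 change of 1 it recovered 22% and 30% for E2 in experiments a and b, 29%, 16% and 19% for the 3 effluent groups in the same order, 21% for 5% against 0.5%, 10% and 9% for the differences and 17% for the controls.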

Results

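Transcript levels were measured in the liver of sexually mature male fathead minnows (Pimephales promelas), a small North American freshwater fish used in toxicity testing, after 14 days of exposure. Experiment a used effluent that had received advanced primary treatment, at 0.5% or 5% of the exposure water. Experiment b used effluent that had received secondary treatment, at 5%. Each experiment had its own control fish in moderately hard water and its own positive control, E2, the usual abbreviation for the female sex hormone estradiol. In experiment a there were 5 control arrays, 4 E2 arrays, 3 arrays at 0.5% effluent and 10 arrays at 5% effluent. In experiment b there were 4 control arrays, 6 E2 arrays and 6 arrays at 5% effluent.

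The arrays carried 15208 probes, of which 13185 were tested. Between 9837 and 12739 probes per array were well above background, and no spot was saturated. The number of arrays limits the precision of every value below. The arrays lay on 5 slides. Slides 1 and 2 held the controls, the E2 arrays and the 0.5% arrays of experiment a, with 3 of the 5% primary arrays. Slide 3 held 4 arrays of 5% primary effluent and the 4 controls of experiment b. Slide 4 held 3 arrays of 5% primary and 4 of 5% secondary effluent, and slide 5 held the 6 E2 arrays of experiment b and 2 arrays of 5% secondary effluent. The files do not pair probes with genes, so probes are named by their identifier and a contig. The word contig stands here for the sequence name that the files give with a probe, whether it begins with FJU or gi. At most 2 probes that rose and 2 that fell are named in each comparison. Levels are log2 signal relative to the 75th percentile of the array, and adjusted p-values are from limma with Benjamini-Hochberg adjustment, two-sided.

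E2 served as the positive control for a response to estrogen. In experiment a, 1286 of 13185 probes differed between E2 and control fish, 545 higher and 741 lower. UF_Ppr_AF_115478 (contig FJU.119.C2) rose 1600-fold, from -1.43 ± 2.86 (SD, n = 5) in the controls to 9.22 ± 0.78 (SD, n = 4) under E2 (log2 change 10.64, SE 1.27, limma adjusted p = 3.18e-07). UF_Ppr_AF_115272 (contig FJU.85.C11) rose 1500-fold, from -0.97 ± 1.67 to 9.59 ± 0.75 (log2 change 10.55, SE 1.16, adjusted p = 6.8e-08). Their sequences are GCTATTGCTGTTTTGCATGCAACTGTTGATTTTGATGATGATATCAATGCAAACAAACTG and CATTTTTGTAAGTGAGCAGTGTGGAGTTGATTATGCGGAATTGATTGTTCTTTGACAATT. UF_Ppr_AF_107994 (contig FJU.131.C2) fell by 6.17 on the log2 scale (SE 0.96, adjusted p = 4.09e-05), from 2.93 ± 1.58 to -3.25 ± 2.09, and was above background on 3 of the 4 E2 arrays. UF_Ppr_AF_111108 (contig FJU.8531.C1) fell by 6.02 (SE 1.63, adjusted p = 0.0158), from 1.86 ± 1.61 to -4.16 ± 4.41, and was above background on 2 of the 4 E2 arrays. Of the probes called higher, 95 were above background on no control array of the experiment. On the first principal component of all arrays, which held 15.1% of the variance, the E2 arrays of both experiments lay between 37.8 and 82.3 and all others between -51.5 and 18.3.

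Fitted with slide as a block, experiment a gave 1123 calls (464 higher, 659 lower), 993 of them among the 1286. Comparisons within a slide took their spread from a fit of every set of arrays that shared group and slide, so a lone array was assumed to vary like the others. Slide 2, with 3 E2 arrays and 2 controls, gave 780 calls (328 higher, 452 lower), and slide 1, where E2 had 1 array against 3 controls, gave 281 (209 higher, 72 lower) on that assumption. UF_Ppr_AF_115478 changed by 13.3 within slide 1 and 7.53 within slide 2, UF_Ppr_AF_115272 by 11.7 and 9.53, and UF_Ppr_AF_107994 by -6.18 and -6.29. Normexp background correction called 711 probes, array weights 793, and a fit of these 2 groups alone 291 (166 higher, 125 lower). Without E2 array 1, 793 probes were called, and UF_Ppr_AF_111108 no longer passed (log2 change -4.38, adjusted p = 0.111).

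**Figure D1:**
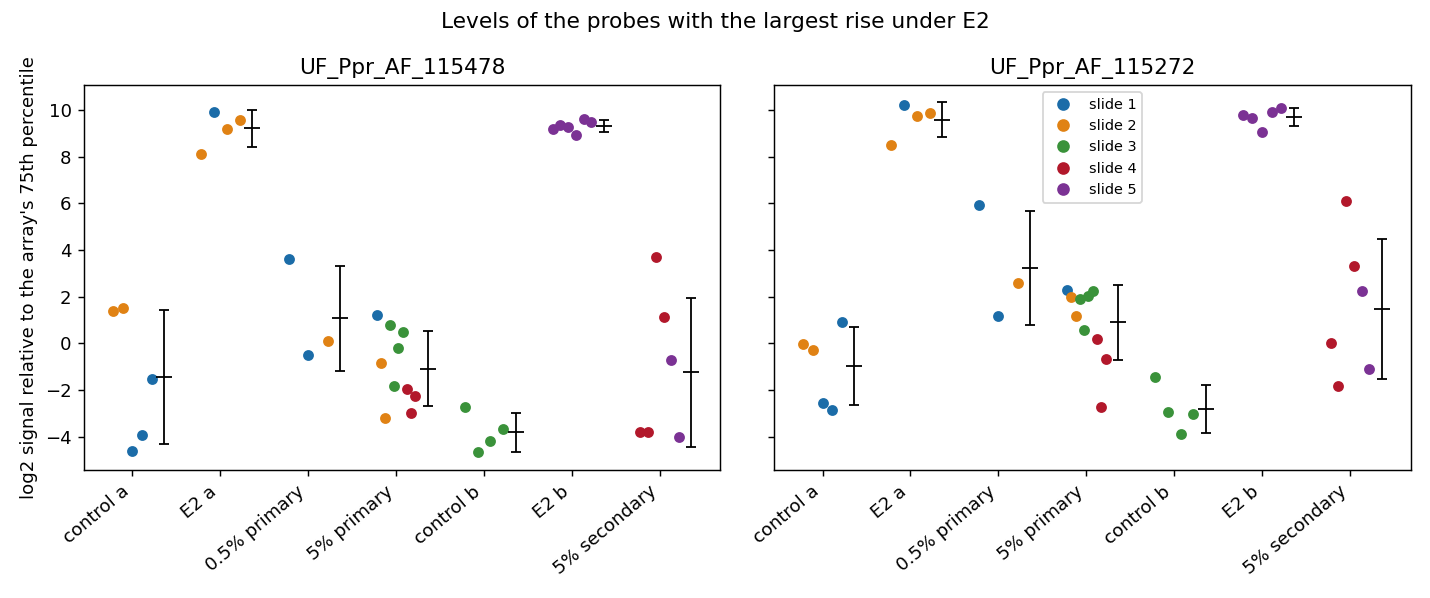
Log2 signal relative to the array's 75th percentile (vertical axis) of UF_Ppr_AF_115478 and UF_Ppr_AF_115272 in each group (horizontal axis). Each point is 1 array coloured by slide, and the bar to its right is the group mean with SD; the E2 arrays of both experiments lie above every other array.

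In experiment b, E2 changed 1651 probes, 723 higher and 928 lower. The same pair of probes led the rise. UF_Ppr_AF_115478 rose 8980-fold, from -3.81 ± 0.84 (SD, n = 4) to 9.32 ± 0.24 (SD, n = 6; log2 change 13.13, SE 1.22, limma adjusted p = 1e-09). UF_Ppr_AF_115272 rose 5930-fold, from -2.83 ± 1.03 to 9.70 ± 0.40 (5 E2 arrays with a usable spot; log2 change 12.53, SE 1.16, adjusted p = 1.08e-09). UF_Ppr_AF_107106 (contig FJU.4503.C1) was lower under E2, at -6.35 ± 2.93 against -0.98 ± 2.47 (adjusted p = 0.0452), and no size is given, as it was above background on 1 of the 6 E2 arrays. UF_Ppr_AF_103513 (contig FJU.9127.C1) fell by 4.86 (SE 1.21, adjusted p = 0.00697), from 1.16 ± 1.79 to -3.70 ± 0.85. Of the probes called higher, 48 were above background on no control array of the experiment. The balance of directions moved with the processing: 43.8% of the calls were higher in the main scaling, 52.4% with quantile normalization (864 higher, 786 lower), and normexp background correction called 866 (504 higher, 362 lower). Array weights called 2630.

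The E2 arrays of experiment b were all on slide 5 and its controls all on slide 3, so the comparison could be made within no slide. A fit with slide as a block, which ties these slides together through the effluent arrays, called 279 probes (202 higher, 77 lower), 182 of them among the 1651. In that fit UF_Ppr_AF_115478 rose by 17 (adjusted p = 0.00013) and UF_Ppr_AF_115272 by 16.6 (adjusted p = 3.1e-05), while UF_Ppr_AF_107106 (adjusted p = 0.65) and UF_Ppr_AF_103513 (-6.26, adjusted p = 0.17) did not pass. Within slide 5, E2 against the 2 secondary effluent arrays gave 717 calls (454 higher, 263 lower). Those 2 arrays, numbers 5 and 6, were exposed to effluent and were the pair of arrays most alike (r = 0.986). Without control array 2 of experiment b, 1076 probes were called. The call on UF_Ppr_AF_107106 ended without any 1 of control arrays 2, 3 and 4 or E2 arrays 1, 2, 3, 5 and 6 (adjusted p between 0.073 and 0.119).

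The response to E2 was compared between the experiments, which shared no arrays. Of the tested probes, 176 rose in both, against 29.9 expected of independent lists, and 144 fell in both, against 52.2. Opposite calls numbered 3 and 15, against 38.4 and 40.6. Across probes, which are not independent replicates, the fold changes had r = 0.355 (Spearman's rho = 0.243, covariance 0.324). Simulated unchanged groups gave r from -0.29 to 0.41, a range that holds the observed r, and a mean covariance of 0.0042 (SD 0.044). When both fits had slide as a block, 77 rose in both, against 7.1 expected, and 8 fell in both, against 3.8, while opposite calls numbered 3 and 3, against 2.7 and 10, so the first of these was no longer below its expectation.

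**Figure D2:**
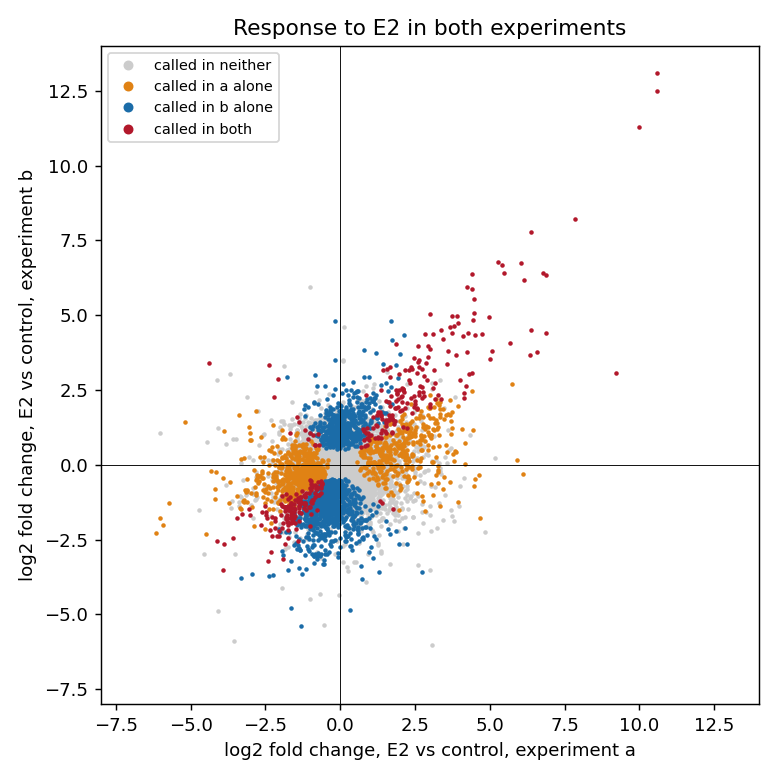
Log2 fold change under E2 in experiment a (horizontal axis) and in experiment b (vertical axis), each point 1 of 13185 probes, coloured by whether it passed adjusted p = 0.05 in neither, 1 or both experiments. The 176 probes that rose in both extend to the upper right corner.

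The size of the E2 response differed between the experiments for 238 probes (79 with a higher value in experiment a, 159 with a lower value). UF_Ppr_AF_101723 (contig FJU.3949.C1) rose by 9.23 in experiment a and 3.07 in experiment b (difference 6.16, SE 1.45, limma adjusted p = 0.0246), and was above background on 2 of the 5 controls of experiment a. UF_Ppr_AF_112541 (contig gi_73731801) changed by 2.73 in experiment a (adjusted p = 0.13, not called) and fell by 3.59 in experiment b (difference 6.32, SE 1.61, adjusted p = 0.039), but was above background on 1 of the 5 controls of experiment a and 2 of the 6 E2 arrays of experiment b. Sizes of these probes are approximate where few arrays were above background. UF_Ppr_AF_109142 (contig FJU.9267.C1) fell by 4.38 in experiment a and rose by 3.39 in experiment b (difference -7.77, SE 1.52, adjusted p = 0.0109), and was above background on 1 of the 4 E2 arrays of experiment a and 1 of the 4 controls of experiment b. UF_Ppr_AF_114701 (contig FJU_SB_30.117.C1) fell by 5.19 in experiment a and changed by 1.44 in experiment b (adjusted p = 0.46, not called; difference -6.63, SE 1.68, adjusted p = 0.0377). Of the 238, 147 were also called between the controls of the experiments in the same direction. The same control arrays enter both contrasts, so this agreement is partly built in.

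The fit with slide as a block called 112 of these differences (46 higher, 66 lower), 33 of them among the 238, and UF_Ppr_AF_109142 passed (-11.20, SE 2.22, adjusted p = 0.013). UF_Ppr_AF_101723 (6.03, SE 2.41, adjusted p = 0.2), UF_Ppr_AF_112541 (3.27, SE 2.64, adjusted p = 0.57) and UF_Ppr_AF_114701 (-8.24, SE 2.78, adjusted p = 0.13) did not. Normexp background correction called 136 differences, replicate number as a block 155 and a fit of the 4 groups alone 80. No slide held both experiments' E2 and control arrays, so there is no value within a slide. The count was 91 without control array 4 of experiment a, 389 and 77 without its E2 arrays 2 and 4, 132 and 135 without control arrays 1 and 2 of experiment b, and 148, 127, 402 and 140 without its E2 arrays 1, 2, 4 and 5. Single left-out arrays ended the calls on UF_Ppr_AF_101723 (E2 array 4 of a and control array 1 of b, adjusted p of 0.0505 to 0.0542), on UF_Ppr_AF_112541 (control arrays 3 and 4 and E2 array 4 of a, control arrays 3 and 4 and E2 arrays 1, 2 and 6 of b, 0.0508 to 0.0919) and on UF_Ppr_AF_114701 (control arrays 2 and 4 and E2 arrays 2 and 4 of a, control array 3 and E2 arrays 1 and 2 of b, 0.0512 to 0.0868).

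The 5% effluent concentration was the level at which the submitters looked for responses. In 5% primary effluent, 116 probes differed from the controls of experiment a, 65 higher and 51 lower. UF_Ppr_AF_107235 (contig FJU.1325.C1) rose 14.9-fold, from 1.90 ± 3.42 (SD, n = 5) to 5.80 ± 1.03 (SD, n = 10; log2 change 3.90, SE 0.94, limma adjusted p = 0.0384). UF_Ppr_AF_105382 (contig gi_73734414) rose 12.2-fold, from -3.89 ± 1.47 to -0.28 ± 1.12 (log2 change 3.60, SE 0.72, adjusted p = 0.0161). UF_Ppr_AF_109968 (contig FJU.11.C1) fell by 3.74 (SE 0.79, adjusted p = 0.0182), from -0.63 ± 0.62 to -4.36 ± 1.22, and was above background on 8 of the 10 exposed arrays. UF_Ppr_AF_103759 (contig FJU.1484.C1) fell by 2.86 (SE 0.62, adjusted p = 0.0234), from 5.83 ± 1.46 to 2.97 ± 0.96. The balance of directions rested on the scaling: 56% of the calls were higher in the main scaling, 39.1% with quantile normalization (50 higher, 78 lower) and 32.7% with each array's median (33 higher, 68 lower).

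When slide was a block, 2 probes were called in 5% primary effluent, both lower, and none of the 4 named probes passed (log2 change 3.44, 3.11, -3.37 and -3.29, adjusted p = 0.59, 0.52, 0.45 and 0.22). Normexp background correction called 61 probes, array weights 218, replicate number as a block 4 and a fit of the 2 groups alone 11. Within slide 2, with 2 exposed arrays and 2 controls, limma called 0 probes (921 at an unadjusted p under 0.05), and within slide 1, with 1 exposed array and 3 controls, also 0 (958), the lone array being assumed to vary like the others. The count of calls was 290, 14, 2 and 77 without control arrays 1, 3, 4 and 5, and 71, 322, 43, 51, 49 and 59 without exposed arrays 2, 3, 6, 7, 8 and 10. Without control array 4 none of the 4 named probes passed (adjusted p up to 0.252), without control array 3 UF_Ppr_AF_107235, UF_Ppr_AF_109968 and UF_Ppr_AF_103759 did not, and UF_Ppr_AF_107235 also did not without exposed array 5, 6, 7 or 8 (adjusted p from 0.0518).

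The 0.5% concentration was described by the submitters as realistic for the environment. In 0.5% primary effluent limma called 0 of 13185 probes, with a smallest adjusted p of 0.65. At an unadjusted p under 0.05 there were 619 probes, where 659 would be expected of unchanged probes. UF_Ppr_AF_115272, which led the rise under E2 together with UF_Ppr_AF_115478, differed from the controls by 4.20 (SE 1.26, adjusted p = 0.96) at 0.5% and by 1.87 (SE 0.94, adjusted p = 0.34) at 5%, and UF_Ppr_AF_115478 by 2.50 (SE 1.38, adjusted p = 1) and 0.35 (SE 1.04, adjusted p = 0.91). None of these passed. As a block, slide left 0 calls in limma (700 at an unadjusted p under 0.05), and within slide 1, with 2 exposed arrays and 3 controls, it called 0 (856). Within slide 2 the exposed group was 1 array, assumed to vary like the others, and 1 probe was called, lower. Without control array 1 limma called 1. In simulated data of 13185 probes, with 100 changed by each size, 60% of log2 changes of 2 and 16% of log2 changes of 1 were recovered for this comparison. The simulated noise was independent between probes and arrays and held no slide difference, unlike these data.

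The 5% and 0.5% primary effluent groups were compared directly. Limma called 0 probes, with 573 at an unadjusted p under 0.05 and a smallest adjusted p of 0.49. Of the probes that fell most at 5%, UF_Ppr_AF_109968 differed by -0.99 (SE 0.94) and UF_Ppr_AF_103759 by -0.41 (SE 0.74) between the concentrations (adjusted p = 1 for both). As a block, slide left 0 calls in limma (500 at an unadjusted p under 0.05), and within slides 1 and 2, on each of which 1 of the groups was a lone array assumed to vary like the others, it called 0 (535) and 2, both higher. Without 0.5% array 3 limma called 1.

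In 5% secondary effluent, 181 probes differed from the controls of experiment b, 43 higher and 138 lower. UF_Ppr_AF_115272 rose 19.6-fold, from -2.83 ± 1.03 (SD, n = 4) to 1.47 ± 3.01 (SD, n = 6; log2 change 4.30, SE 1.11, limma adjusted p = 0.0436), with single exposed arrays between -1.81 and 6.12. UF_Ppr_AF_118777 (contig FJU.5877.C1) rose 6.23-fold, from -2.65 ± 2.49 to -0.01 ± 0.64 (log2 change 2.64, SE 0.60, adjusted p = 0.026). UF_Ppr_AM_119685 (contig FJU.10034.C1) was at least 3.27-fold lower (adjusted p = 0.0187) and UF_Ppr_AF_109647 (contig gi_73469785) at least 2.74-fold lower (adjusted p = 0.00821) on the exposed arrays, where neither was well above background. These are bounds against the dimmest signal that counted as well above background on each array. Both signals went with slide 3, which held these controls: UF_Ppr_AM_119685 was above background on 7 of its 8 arrays and UF_Ppr_AF_109647 on 8 of 8, 5% primary arrays included, and each on 1 of the 30 arrays elsewhere. On slide 3 the 5% primary arrays had UF_Ppr_AF_109647 at -5.07 to -4.46 and the controls at -4.70 to -4.13, so neither fall can be laid to the effluent apart from the slide. In the main scaling 23.8% of the calls were higher, against 39.3% with quantile normalization (44 higher, 68 lower) and 30.9% with each array's median (43 higher, 96 lower).

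No slide held both controls and 5% secondary arrays, so there was no value within a slide. Once slide was added as a block, limma called 0 probes, with 877 at an unadjusted p under 0.05, and none of the 4 named probes passed. UF_Ppr_AF_115272 then stood at 7.49 (SE 1.72, adjusted p = 0.22) and UF_Ppr_AF_118777 at 2.53 (SE 1.01, adjusted p = 0.63), while the fitted falls of UF_Ppr_AM_119685 and UF_Ppr_AF_109647, which include signal below background, shrank from -3.47 to -1.80 (SE 1.21) and from -2.89 to -0.82 (SE 0.56; adjusted p = 0.88 for both). Normexp background correction called 6 probes, all lower, array weights 493, and an average of exposed arrays 5 and 6, tried after seeing the data, 74. The count of calls was 73, 47, 47 and 62 without control arrays 1 to 4, and 68, 67, 93, 114 and 74 without exposed arrays 1, 3, 4, 5 and 6. Single left-out arrays ended the calls on UF_Ppr_AF_115272 (control arrays 1 to 4 and exposed arrays 1, 3, 4 and 5, adjusted p of 0.0597 to 0.141), on UF_Ppr_AF_118777 (control arrays 1 and 4 and exposed array 6, 0.0508 to 0.124) and on UF_Ppr_AM_119685 (control arrays 2 and 3, 0.0729 to 0.0831).

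The effect of 5% effluent was compared between primary and secondary treatment as a difference of differences. It was called for 336 probes, 291 with a higher value in experiment a (86.6%) and 45 with a lower one. UF_Ppr_AF_109968 fell by 3.74 in primary effluent and changed by 0.88 in secondary effluent (adjusted p = 0.81; difference -4.61, SE 1.21, limma adjusted p = 0.0332). UF_Ppr_AF_103759 fell by 2.86 and changed by 0.67 (adjusted p = 0.81; difference -3.53, SE 0.96, adjusted p = 0.0404). UF_Ppr_AF_112541 changed by 2.37 (adjusted p = 0.21) and -3.16 (adjusted p = 0.17), a difference of 5.53 (SE 1.47, adjusted p = 0.0349), and was above background on 1 of the 5 controls of experiment a. UF_Ppr_AM_119685 was also called, with a higher value in experiment a (adjusted p = 0.0215), but no size is given, as it was above background on 0 of the 5 controls of experiment a and 0 of the 6 secondary arrays. All 4 probes were also called between the controls of the experiments in the same direction, as were 223 of the 336. The same control arrays enter both contrasts, so this agreement is partly built in. These differences lie at least in part between the control arrays, whether in the fish or in the noise of those arrays. The exposed means of UF_Ppr_AF_103759, 2.97 in primary and 1.29 in secondary effluent, lay the other way round from the difference. With quantile normalization 61% of the calls were higher (155 higher, 99 lower), and with each array's median 69.6% (206 higher, 90 lower).

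Once slide was added as a block, limma called 0 of these differences, with 1058 at an unadjusted p under 0.05, and none of the 4 named probes passed. UF_Ppr_AF_109968 then stood at -4.20 (SE 1.80, adjusted p = 0.57), UF_Ppr_AF_103759 at -4.52 (SE 1.41, adjusted p = 0.43) and UF_Ppr_AF_112541 at 3.84 (SE 2.26, adjusted p = 0.7), and the adjusted p of UF_Ppr_AM_119685 was 0.77. Over all 336 called differences the block left a median of 30.8% of the effect. Normexp background correction called 0 (973 at an unadjusted p under 0.05), array weights 714 and the strict filter 219. The count was 189 and 209 without control arrays 4 and 5 of experiment a, 197, 171 and 202 without control arrays 2, 3 and 4 of experiment b, and 214 without secondary array 1. Single left-out arrays ended the calls on UF_Ppr_AF_109968 (control arrays 2, 4 and 5 of a, control arrays 1, 2 and 4 of b, secondary arrays 1 and 4), UF_Ppr_AF_103759 (control arrays 3 and 4 of a, primary arrays 5 and 7, control arrays 3 and 4 of b, secondary arrays 1, 2 and 4), UF_Ppr_AF_112541 (control arrays 3, 4 and 5 of a, primary array 5, control arrays 3 and 4 of b, secondary arrays 3, 5 and 6) and UF_Ppr_AM_119685 (control array 4 of a, control arrays 2 and 3 of b), with adjusted p between 0.0512 and 0.117 for these. The 5% primary and 5% secondary arrays of slide 4, compared directly, differed in 222 probes (186 higher in primary, 36 lower).

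**Figure D3:**
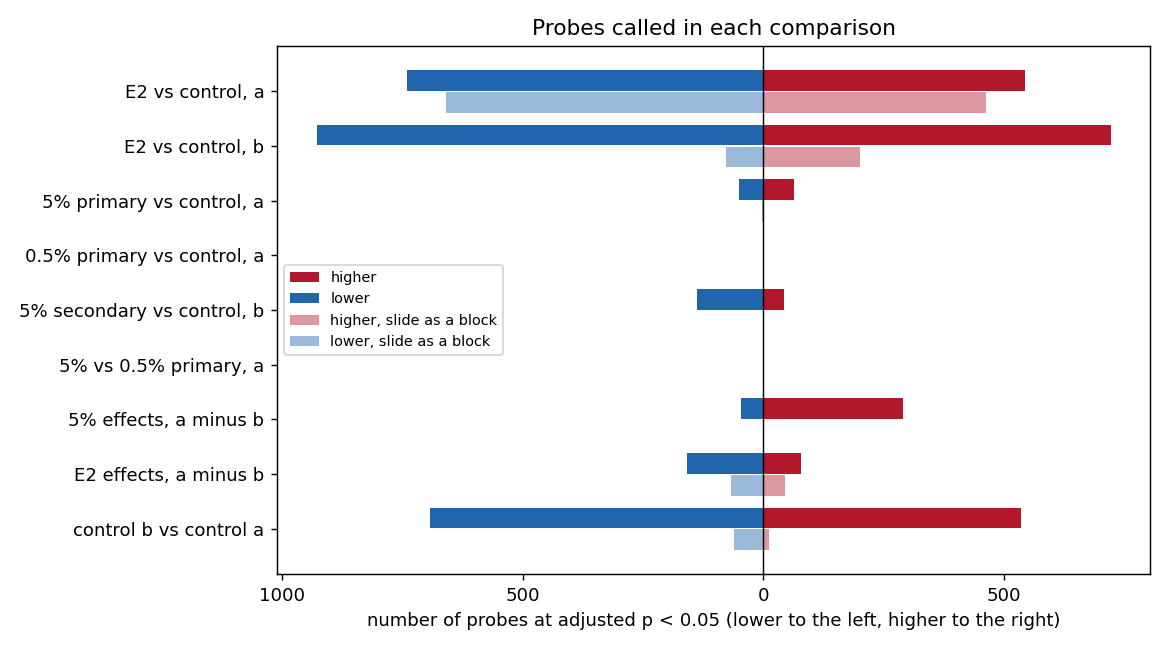
Number of probes (horizontal axis) called lower (to the left) and higher (to the right) in each comparison (vertical axis), without (dark bars) and with (pale bars) slide as a block. The E2 comparison of experiment a falls from 1286 to 1123 calls with the block, and that of 5% secondary effluent from 181 to 0.

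The probes that responded to E2 and to 5% effluent were set against each other within each experiment. In experiment a, 7 rose in both E2 and 5% primary effluent, against 2.7 expected of independent lists, 11 fell in both, against 2.9, and 1 went opposite ways. In experiment b, 29 rose in both E2 and 5% secondary effluent, against 2.4, 103 fell in both, against 9.7, and 2 went opposite ways. Both members of each pair used the same controls. In experiment b these lay on slide 3 alone and the exposed arrays on slides 4 and 5, so a slide difference would enter both members. Splitting the controls does not remove it. With slide as a block, 5% secondary effluent kept 0 calls and 5% primary effluent 2, so few or none could be shared. With the controls split between the members, which left fewer for each, the 18 shared calls of experiment a became a median of 0 (0 to 1 over 10 splits) and the 132 of experiment b a median of 2.5 (0 to 7 over 6 splits).

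Across probes, the fold changes of E2 and 5% primary effluent had r = 0.313 (rho = 0.283) and those of E2 and 5% secondary effluent r = 0.496 (rho = 0.498). Simulated unchanged groups gave 0.55 (0.3 to 0.72) and 0.6 (0.38 to 0.76) from the shared controls alone. The covariance was 0.181 for primary effluent, against a simulated 0.14 (SD 0.04), a difference of 0.039, and 0.291 for secondary effluent, against 0.17 (SD 0.045), a difference of 0.12. The simulations shuffled the arrays without regard to slide, and split controls of experiment b all stayed on slide 3. The values for secondary effluent can therefore not be told apart from a slide difference. With split controls the median r was 0.083 (-0.031 to 0.21) and 0.18 (0.17 to 0.22). The 0.5% and 5% primary effluent changes had r = 0.575 (rho = 0.553), with a covariance of 0.201 against a simulated 0.15 (SD 0.049) and a median r of 0.093 (0.05 to 0.34) with split controls. The 5% primary and 5% secondary changes, which share no arrays, had r = -0.0755 (rho = -0.0841; simulated -0.3 to 0.36), and 5 probes were called in the same direction in both and 3 in opposite directions.

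The shared calls in experiment a numbered 44, 10, 4 and 0 without control arrays 1 to 4, 11 without E2 array 1, and 7, 34, 11, 5, 4, 6, 9 and 5 without 5% arrays 2, 3, 5, 6, 7, 8, 9 and 10. In experiment b they numbered 63, 38, 42 and 52 without control arrays 1 to 4 and 58, 53, 77, 78 and 60 without 5% arrays 1, 3, 4, 5 and 6.

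The control fish of the experiments differed from each other in 1229 probes, 537 higher and 692 lower in experiment b. UF_Ppr_AF_108914 (contig FJU.9640.C1) was higher, at -0.03 ± 4.04 (SD, n = 4) against -6.42 ± 2.29 (SD, n = 5; limma adjusted p = 0.0177), and no fold is given, as it was above background on 2 of the 5 controls of experiment a. UF_Ppr_AF_116092 (contig FJU.4306.C6) was 56.1-fold higher, at 4.03 ± 0.85 against -1.79 ± 1.32 (log2 change 5.81, SE 1.34, adjusted p = 0.0069). UF_Ppr_AF_103759 was lower, with a log2 change of -5.20 (SE 0.76, adjusted p = 8.34e-05), at 0.62 ± 1.37 against 5.83 ± 1.46. UF_Ppr_AF_115622 (contig gi_72742014) was also lower, with a log2 change of -4.59 (SE 0.78, adjusted p = 0.000516), at -0.63 ± 0.76 against 3.96 ± 1.81.

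The controls of the experiments shared no slide. The block for slide left 73 calls (12 higher, 61 lower), 62 of them among the 1229. UF_Ppr_AF_103759 and UF_Ppr_AF_115622 passed (adjusted p = 0.018 for both), and UF_Ppr_AF_108914 (adjusted p = 0.24) and UF_Ppr_AF_116092 (7.66, SE 2.07, adjusted p = 0.092) did not. Normexp background correction called 400 probes and a fit of the 2 groups alone 657. The count was 784 and 587 without control arrays 3 and 4 of experiment a and 700, 736 and 699 without control arrays 2, 3 and 4 of experiment b. Leaving out control array 4 of experiment a or control array 1, 2 or 3 of experiment b ended the call on UF_Ppr_AF_108914 (adjusted p of 0.0516 to 0.0669).

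Signal over background was measured on the negative control spots of each array. Their mean net signal was 27.5 on slide 1, 19 on slide 2, 19.5 on slide 3, 28.1 on slide 4 and 26 on slide 5, with an SD between arrays of a slide from 0.35 to 1.5. Within a slide the groups lay close together, so that the 5% primary arrays took the level of whichever slide they were on.

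**Figure D4:**
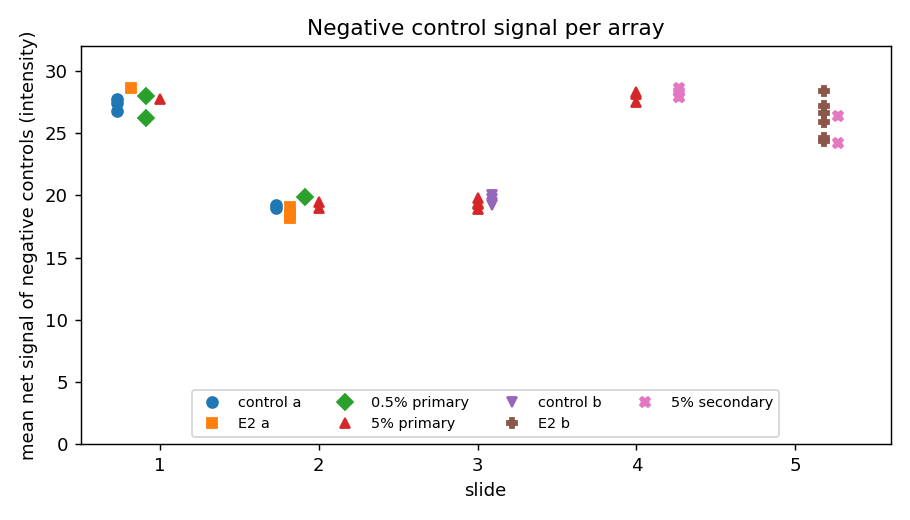
Mean net signal of the negative control spots (intensity, vertical axis) of each array by slide (horizontal axis), with a marker for each group. Slides 2 and 3 average 19 and 19.5, and slides 1, 4 and 5 average between 26 and 28.1.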

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

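The tests of the slide and of the slides' background level were chosen only after the results were seen; the other splits of the arrays and the test of array brightness were written before. In 5 of 73 probe and group sets of 4 to 10 arrays, 1 array stood far from the others, and chance gives about 1 in 20 sets. UF_Ppr_AF_107106 was at -0.368 on E2 array 4 of experiment b, against -7.78 to -7.29 on the others, and at -4.68 on control array 1, against 0.188 to 0.317. UF_Ppr_AM_119685 was at -6.37 on 5% secondary array 1, against -8.16 to -7.76, although it was above background on none of them. UF_Ppr_AF_109142 was at -7.11 on control array 3 of experiment a, against -2.23 to -0.972, and UF_Ppr_AF_108914 at -6.08 on control array 4 of experiment b, against 1.83 to 2.22.

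The E2 effect differed between the experiments for 238 probes. By the test of that difference, UF_Ppr_AF_112541 (6.32) and UF_Ppr_AF_101723 (6.16) had a higher effect in experiment a, and UF_Ppr_AF_109142 (-7.77) and UF_Ppr_AF_114701 (-6.63) a lower one. The count was 91 without control array 4 of experiment a, 389 and 77 without its E2 arrays 2 and 4, 132 and 135 without control arrays 1 and 2 of experiment b, and 148, 127, 402 and 140 without its E2 arrays 1, 2, 4 and 5. When slide was a block, UF_Ppr_AF_109142 alone of these 4 passed (adjusted p = 0.013).

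The arrays of each comparison were also divided in other ways into groups of the same sizes, over 13043 probes with no missing value. For E2, 1 of 100 divisions, the real one, gave as many calls in experiment a (1257, highest other 533) and 1 of 100 in experiment b (1647, highest other 400). The same held, with 1 of 100 each, for 5% primary effluent (115, highest other 98), 5% secondary effluent (180, highest other 40), the difference of the 5% effects (337, highest other 260), the difference of the E2 effects (236, highest other 163) and the controls (1230, highest other 625). If arrays are exchangeable, which fish of 1 aquarium may not be, this argues against a chance division of the groups compared. The margin was narrow for 5% primary effluent, whose count ran from 2 to 322 with single arrays left out. For the differences of effects the divisions exchanged arrays between the experiments, whose controls differed. They therefore do not test whether the effects were equal. The divisions ignored the slides, which largely went with the groups, so they do not exclude the slide, and 5% primary effluent kept 2 calls with slide as a block. For 0.5% primary effluent (real 0, highest other 40) and for 5% against 0.5% (real 0, highest other 120) the test decides nothing, since all 56 and all 100 divisions give at least 0 calls. What sets the divisions with 40 and 120 calls apart was not tested.

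The first pattern weighed is the 181 probes called in 5% secondary effluent, whose controls lay on slide 3 and whose exposed arrays lay on slides 4 and 5. Array brightness is argued against, since its slope within other groups predicted -0.000747 of the effect (2 standard errors 0.0234). So is the background level of the slides as the whole cause. Slide 1 stood to slide 2 in negative controls (27.5 and 19) as slide 4 to slide 3 (28.1 and 19.5). Yet slide 1 lay above slide 2 by 0.0499 of the effect (2 standard errors 0.0996). The processed signal was already background-subtracted, and which way a higher background would move dim probes was not tested. On all 181 the 5% primary arrays of slide 4 lay above those of slide 3 by 0.98 in the direction of the effect of 1.72. That is a share of 0.567 (2 standard errors 0.0709), whose interval reaches below the bound of 0.5 set for it. On the 138 that fell the share was 0.624 (2 standard errors 0.113), so the slide may account for most of the falls. On the 43 that rose it was 0.352 (2 standard errors 0.108), under the bound. But the spread in the fit included these arrays, so probes that shifted between slides were less likely to be called. The share may thus be too low, and the slide stays open for the rises too. A response to the effluent stays open, untested apart from the slide: the block for slide left a median of 39.7% of the effects, 31.3% of the falls and 66% of the rises, and the count of 181 fell to 73, 47, 47 and 62 without control arrays 1 to 4 and to 68, 67, 93, 114 and 74 without exposed arrays 1, 3, 4, 5 and 6.

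The second pattern is the 116 probes called in 5% primary effluent, which lost all but 2 calls with slide as a block. Brightness predicted 0.00511 of the effect (2 standard errors 0.0107). The 5% primary arrays of slides 3 and 4 lay above those of slides 1 and 2, where the controls were, by 0.131 of the effect (2 standard errors 0.297). The share was 0.196 (2 standard errors 0.275) for the rises and 0.0415 (2 standard errors 0.368) for the falls alone. All lay under the bound of 0.5. But these arrays also set the spread in the fit, so probes that shifted between slides were less likely to be called. That may lower the share, so the slide is not excluded as the cause. With the block the effects kept a median of 86% of their size while their errors grew (UF_Ppr_AF_107235 from 3.90, SE 0.94, to 3.44, SE 1.25), since 3 of the 10 exposed arrays shared a slide with controls. A response to the effluent may be the source, as a hypothesis, and the count ran from 2 without control array 4 and 14 without control array 3 to 322 without exposed array 3, with 290 and 77 without control arrays 1 and 5 and 71, 43, 51, 49 and 59 without exposed arrays 2, 6, 7, 8 and 10.

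The third pattern is the 1229 probes that differed between the controls of the experiments, of whose effect brightness predicted -0.0018 (2 standard errors 0.0298). The 5% primary arrays of slide 3, where control b lay, stood above those of slides 1 and 2, where control a lay, by 0.208 of the effect (2 standard errors 0.163), under the bound of 0.5. The share was 0.0763 (2 standard errors 0.213) for the 692 probes lower in experiment b, and 0.358 (2 standard errors 0.15) for the 537 higher, whose interval reaches the bound. Here too these arrays helped to set the spread by which probes were called, which may lower the share. The slide is therefore not excluded, in whole or in part. The block left a median of 80.4% of the effects. A difference between the fish or the water of the experiments could be the source: on slide 3 the 5% primary arrays differed from control b in 541 probes (375 higher, 166 lower), which the slide does not explain but which also holds the effect of the effluent. The count was 784 and 587 without control arrays 3 and 4 of experiment a and 700, 736 and 699 without control arrays 2, 3 and 4 of experiment b.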

How the results depend on the processing

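The alternatives without arrays of low weight, with 2 arrays averaged, and of other scalings for the E2 lists were chosen after seeing the data. Of 372 values of named probes under alternatives other than left-out arrays, 309 kept their call and direction, 63 lost the call and 0 changed direction. Slide as a block lost 19 calls and kept 9, normexp lost 11 and kept 17, and the replicate block lost 10 and kept 18. The 2-fold minimum could lose none and the strict filter hardly any, since the probes were chosen for large changes and signal above background. The deposited values nearly repeat the array median. The cause was not tested for any change below, unless stated. Calls ranged from 793 to 1431 for E2 in experiment a with single arrays left out, from 1076 to 1573 in experiment b, from 2 to 322 for 5% primary, from 0 to 1 for 0.5% primary, from 47 to 211 for 5% secondary, from 0 to 1 for 5% against 0.5%, from 171 to 433 for the difference of 5% effects, from 77 to 402 for that of E2 effects and from 587 to 1207 for the controls. Overlaps of E2 and 5% calls ranged from 0 to 44 in experiment a and 38 to 151 in b. Correlations ranged from 0.261 to 0.381 (E2, 5% primary), 0.463 to 0.538 (E2, secondary), 0.398 to 0.66 (0.5%, 5% primary), 0.304 to 0.383 (E2 in both) and -0.106 to -0.032 (5% primary, secondary). The array median, the deposited log2 values, a 2-fold minimum and the trended robust variance moved no total of calls by over 1.5 times, but with the array median and the deposited values 33 and 29 probes were called higher in 5% primary, against 65, and 90 and 89 lower in the difference of 5% effects, against 45. Quantile normalization called 112 for 5% secondary, and moved the E2 list that rose to -0.0265 in 5% primary and 0.0284 in 5% secondary. Normexp called 711 and 866 for E2 in a and b, 61 for 5% primary, 6 for 5% secondary, 0 for the difference of 5% effects (973 at an unadjusted p under 0.05 in limma), 136 for that of E2 effects and 400 for the controls. It gave overlaps of 6 and 6, correlations of 0.364 (E2, secondary) and 0.115 (5% primary, secondary), and E2 lists in 5% secondary at 0.343 (rose) and 0.0191 (fell). Without a filter the overlap in a was 10, and with the strict filter, which tests fewer probes, the difference of 5% effects had 219 calls. Array weights called 793 and 2630 for E2, 218 for 5% primary, 493 for 5% secondary and 714 for the difference of 5% effects. Slide as a block left 279 calls for E2 in b, 2 for 5% primary, 0 for 5% secondary (877 at an unadjusted p under 0.05), 0 for the difference of 5% effects (1058 unadjusted), 112 for that of E2 effects and 73 for the controls. Fits of the compared groups alone, which have fewer arrays, called 291 for E2 in a, 11 for 5% primary, 80 for the difference of E2 effects and 657 for the controls. Without the 4 arrays of weight under 0.6, 97 were called for 5% secondary, and with secondary arrays 5 and 6 averaged 74. With controls split, overlaps had medians of 0 and 2.5 and correlations 0.083, 0.18 and 0.093, but each comparison then also had fewer controls. Replicate numbers did not pair the arrays, since 87 pairs of the same number had a median correlation of -0.0018 (-0.24 to 0.27) and 4 of 38 arrays correlated best with their own number. The replicate block called 4 for 5% primary, 1 for 5% against 0.5% and 155 for the difference of E2 effects, with an overlap of 1 in a. Gene lists and cell type markers were not run under any alternative, because 0 members were measured. Signal over background, reached by 9837 to 12739 probes per array, limits what can be said of dim probes, whose median residual SD was 0.759 in the dimmer part of the tested probes against 0.465 in the brighter part.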

Other observations

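The tests of the E2 lists and of the leading E2 probes in effluent fish, and the comparisons of array pairs, were chosen after the results were seen. Contig families, groups of contigs with the same cluster number, were tested as sets, 180 times over 20 families. Limma's camera, which sets a family against the other probes, with a preset correlation called family FJU.4411 in 5% primary effluent (adjusted p = 0.0017, median log2 change -0.66, 0 of its 5 probes called) and in 5% against 0.5% (adjusted p = 0.0018). With an estimated correlation the adjusted p was 0.25 and 0.26, and camera called no family. Limma's fry, which asks whether a family's own probes moved 1 way on balance, called 2 families under E2 in experiment a, 6 in experiment b, 1 in 5% primary effluent (FJU.4411, adjusted p = 0.031), 1 in the difference of the 5% effects (FJU.393, adjusted p = 0.044) and 0 in the other comparisons. Its test of mixed directions gave the same highest possible adjusted p for every family in every comparison. It therefore says nothing about movement in mixed directions. FJU.541 was called under E2 in both experiments (adjusted p = 7.9e-06 and 0.0056, median log2 change -1.20 and -0.70, 1 of its 6 probes called in each). When slide was a block, fry kept 2 families under E2 in experiment a, FJU.541 (adjusted p = 0.0001) and FJU.582 (adjusted p = 0.03), and called 0 elsewhere. The median correlation of a family's probes over the arrays ran from -0.064 to 0.35, against 0.0066 for random pairs of probes. Of 436 contigs with both an AF and an AM probe, the letters not being explained in the sources used here, the median correlation of the pair was 0.17, with 74 above 0.5 and 110 below 0. Both probes were called under E2 for 9 contigs in experiment a, all 9 in the same direction, and for 11 in experiment b, 8 of them in the same direction.

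A partial E2-like response in the effluent fish was put as a hypothesis, tested on probes that changed at least 8-fold under E2 in the other experiment, with exact permutation p-values over 6 tests. The 81 probes that rose in experiment b differed by 0.161 in 5% primary effluent (SE 0.118, exact p = 0.164, adjusted p = 0.328, 2 of 10 arrays above all controls) and 0.187 in 0.5% primary effluent (SE 0.125, exact p = 0.25, adjusted p = 0.375, 0 of 3 arrays), where E2 moved them by 3.79. With slide as a block these were 0.263 (2 standard errors 0.522) and 0.165 (2 standard errors 0.512), within slide 1 they were 0.533 and 0.203, and within slide 2 they were -0.085 and 0.195. They were 0.261 and 0.285 without control array 1, and the second was 0.116 without 0.5% array 3. On slide 1 the 5% group, and on slide 2 the 0.5% group, was 1 array. The 33 probes that fell in experiment b were higher, not lower, by 0.875 in 5% primary effluent (SE 0.23, permutation p = 0.00833, adjusted p = 0.05, 7 of 10 arrays above all controls) and by 0.531 in 0.5% (SE 0.248, exact p = 0.0536, adjusted p = 0.161, 2 of 3 arrays), against an E2 change of -0.97. At 0.5% the shift was 0.541 with slide as a block (2 standard errors 0.481), 0.517 within slide 1 and 0.63 within slide 2, but other scalings gave 0.361 (2 standard errors 0.616) to 0.634 (2 standard errors 1.23), and the 25 brighter probes of the list 0.58 (SE 0.377), so nothing is decided at 0.5%. At 5% it was 0.406 with slide as a block (2 standard errors 0.49), 0.987 within slide 1 and 0.035 within slide 2, and the exposed arrays averaged -2.23 on slide 3, which also held the controls that the list was chosen on, against -2.74, -3.36 and -2.93 on slides 1, 2 and 4. The slide may account for part of it, so nothing is decided at 5% either, where the adjusted p lay between 0.04 and 0.222 over 4 other scalings. In 5% secondary effluent the 124 probes that rose in experiment a differed by -0.0446 (SE 0.173, exact p = 0.8), where E2 moved them by 2.62, and the 41 that fell by -0.128 (SE 0.223, exact p = 0.562, adjusted p = 0.674, 2 of 6 arrays below all controls), where E2 moved them by -0.82. The first ran from -0.167 to 0.0267 with single arrays left out, above 0 without control array 2 or exposed array 3 or 4, and beyond 1.5 times apart without control arrays 1, 3 and 4 (-0.03, -0.0167 and -0.167) and exposed array 1 (-0.144). The second ran from -0.239 to 0.0485, above 0 without control array 2, with -0.239 and -0.195 without control arrays 3 and 4 and -0.225, -0.0682 and -0.0742 without exposed arrays 4, 5 and 6. The block for slide gave -0.383 (2 standard errors 0.981) and 1.19 (2 standard errors 1.1), with no value within a slide. These tests decide for none of the lists. Over the 4 other scalings the list that rose ran from -0.0265 (quantile normalization) to 0.169 (normexp) in 5% primary effluent and from 0.0481 to 0.255 in 0.5%. In 5% secondary effluent it ran from -0.00628 (deposited values) to 0.343 (normexp), and its 75 brighter probes stood at 0.0929 (SE 0.21).

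On slides 1 and 2, which held controls and primary effluent arrays together, UF_Ppr_AF_115272 was higher in effluent fish, 3 arrays at 0.5% and 3 at 5%, than in the controls of the same slide by 3.36 (2 standard errors 1.93), on 3 of 3 exposed arrays of slide 1 and 3 of 3 of slide 2. The exact p from permutation within slides was 0.005, the smallest it can give (adjusted p = 0.01 over 2 probes), with differences of 4.63 on slide 1 and 2.09 on slide 2. UF_Ppr_AF_115478 differed by 1.02 (2 standard errors 1.81, exact p = 0.535), with 4.8 on slide 1 and -2.76 on slide 2. The other 5% primary arrays lay at 0.56 to 2.23 on slide 3 and -2.72 to 0.21 on slide 4, against controls of experiment a at -2.87 to 0.93. Over all slides the mean of UF_Ppr_AF_115272 was higher at 0.5% (3.23, SD 2.43) than at 5% (0.90, SD 1.62), against the order of concentration, a difference that was not called. An E2-like rise of UF_Ppr_AF_115272 on slides 1 and 2 may be present, as a hypothesis that UF_Ppr_AF_115478 and the arrays of slide 4 leave undecided.

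Some arrays were unusually alike. The 5% secondary arrays 5 and 6, both on slide 5, had r = 0.986, with 16 of 9590 probes above background on both at least 4-fold apart. The 0.5% primary array 3 on slide 2 and 5% primary array 8 on slide 4 had r = 0.9724 across groups and slides, with 107 of 9594 probes at least 4-fold apart. The next pair, E2 arrays 1 and 2 of experiment b, had r = 0.9663, with 165 of 9848 probes that far apart. Dim probes made up most of the 336 differences of the 5% effects, of which 0.128 lay in the brighter part of the tested probes. The share was 0.171 for the 181 calls of 5% secondary effluent and 0.698 for the 5% primary calls.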
